A study of Homo sapiens with 4 samples.

How the data were processed

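Human embryonic stem cells of the NKX2-5(eGFP/w) line, an established reporter line with a fluorescent protein gene in the locus of the cardiac transcription factor NKX2-5, were differentiated towards cardiomyocytes in culture, per the labels' protocols. Cells were synchronised with dexamethasone, a synthetic glucocorticoid that sets the phase of clock genes in culture, and sampled in triplicate every 4 h for 48 h. RNA was read by CEL-Seq, which barcodes each sample, amplifies the RNA by in vitro transcription and reads tags near the 3′ end of transcripts. Undifferentiated cells (D0) were sequenced at 48 h alone. Cells at day 15 (D15) and day 30 (D30) of differentiation were sequenced at all 12 time points from 4 h to 48 h. The hours are those of the labels, whose column names use zeitgeber notation. Groups, time points and replicate numbers were taken from the labels and the column names. The D15 course was sequenced as 2 library parts, and the column names do not say which part holds which library.

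The deposited values are whole-number counts per gene and library, in one table per day, with totals that differ between libraries. Reads were 75 bp paired-end from a NextSeq500, per the labels' protocols. BWA 0.6.2-r126 and the genome builds hg19 and GRCh37 are named in the submitters' processing notes. The counting tool, the annotation and any use of molecular identifiers are not given in the sources used here. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. A list of barcode sequences was not used. Each table lists its own set of genes: 15081 at D0, 19414 at D15 and 18049 at D30, with 14435 in common to the 3 tables and 17482 to D15 and D30. An entry of the D15 table that is no gene holds a running number per column, from 4 to 39, in place of counts. It stayed out of library sizes and tests, as did the spike-in entries, which held at most 3 counts per table. No gene coordinates are given, because the reference at hand, GENCODE 29, is for another build than the one named in the processing notes; it served only to look up chromosomes and the GC content of transcript ends by gene symbol.

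Total counts per library ran from 1026156 to 1818855 at D0 (median 1202380), from 162219 to 1170556 at D15 (median 356138) and from 153708 to 737207 at D30 (median 447579). A count of 0 in a library allows up to 3 counts, or 18.5 CPM (counts scaled to the library total) in the shallowest D15 library, 19.5 in the shallowest D30 library and 2.92 in the shallowest D0 library. In the deepest libraries the same floor was 2.56, 4.07 and 1.65 CPM. All other CPM use totals adjusted by TMM over the libraries of the comparison, or over the libraries of one day for the courses and for levels outside a comparison. The CPM of one gene in the same libraries therefore differ between comparisons. No library fell under 0.1 of the median total of its table, the limit set for leaving one out. A chi-square of the counts per degree of freedom, over genes with at least 20 counts in a pair of replicates, was at least 4.34 at D0, 2.06 at D15 and 1.68 at D30, so no pair of libraries looked like a repeated deposit. The labels do not say whether the triplicates were separate cultures, and the p-values measure only the spread between these libraries, which may be technical.

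Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with edgeR's default filter (minimum count 10) on the time points or days, libraries were scaled by TMM, and tests used edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from that test unless another is named. The 24-h test fitted a cosine and a sine of period 24 h beside a linear trend, separately at D15 and D30, and tested both terms jointly over 7274 and 8068 genes. Its size is the peak-to-trough difference of the fitted curve in log2 units, with the hour of the peak. The linear trend of the same fits is given as the log2 change from 4 h to 48 h. The difference in rhythm between days was tested by the interaction of day with both terms over 9960 genes. Its size is the peak-to-trough of the difference between the fitted 24-h curves of D30 and D15. That size mixes amplitude and phase and does not say which day holds the larger rhythm. At 48 h, D15 and D30 were each compared with D0 in a fit of the 9 libraries over 8287 genes common to the tables. Deviations of same-numbered D0 and D15 libraries from their group means correlated at 48 h (r = 0.24, 0.32 and 0.14, from the data alone, since the labels give no origin of the numbers), so the fit with the replicate number as a block was set beside this comparison. D30 was compared with D15 over the matched time points, with time point as a factor, over 6956 genes. Values after ± are standard errors for fitted values and standard deviations for CPM. Where a group held 1 to 3 counts of a gene, its fold is given as a ratio with an exact 95% counting interval, and where it held none, as a bound against a floor of 3 counts over the group.

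Lists of genes were fixed before the data were examined, as were the tests and the rule for naming genes; the closing section gives what was added afterwards. The 22 lists cover the core clock, glucocorticoid-responsive genes, pluripotency, sarcomere, cardiac transcription factors, calcium handling and ion channels, genes raised in mature cardiomyocytes, fetal cardiomyocyte genes, fatty acid oxidation, oxidative phosphorylation, glycolysis, cell cycle, fibroblast and matrix, smooth muscle, endothelial, epicardial, endoderm, epithelial and neural markers, oxidative stress, heat shock and the unfolded protein response, and cytosolic ribosomal proteins. Lists with at least 3 tested genes were compared with other genes by camera at a preset correlation of 0.01, again with an estimated correlation, and by fry, which asks whether a list's genes move on balance one way without comparing them with other genes. In the courses, the called members of a list were set against the other tested genes by Fisher's exact test, one-sided. Named genes are the 10 called genes with the smallest p in each 24-h test and in the difference, the 5 called genes with the smallest p in each direction of a trend, the 10 called genes with the largest fold in each direction of a day comparison among those at 50 CPM or more in the higher group (and with no overlap between groups at 48 h), all tested core clock genes, and from each list up to 2 called members per direction or, if none was called, the 2 with the smallest p. Values of 2 genes that meet this rule are not used here, while the counts of called genes and members of lists include them.

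GC content was that of the last 500 bases of the longest transcript of a symbol, found for 94% of the genes in the 48 h comparisons and 94.4% in D30 against D15. A GC offset was fitted per library by lowess (span 0.3) of its log2 counts against GC content. Each test was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 genes changed. A simulated 2-fold rhythm was recovered for 56.9% of the changed genes tested at D15 and 79.1% at D30, and a 4-fold one for 98.5% and 100%. For the difference in rhythm the shares were 37.5% at 2-fold and 79.4% at 4-fold. The trends gave 57.8% at D15 and 68.2% at D30 at 2-fold, the 48 h comparisons 41% at D15 and 33.8% at D30, and the comparison of D30 with D15 100%. Between 3 and 8 unchanged genes were called in each simulation. The simulated genes varied independently, while random orders of the real D15 time points called up to 1156 genes. Variation shared by the genes of a library is missing from the simulation, so these shares and counts may be too favourable.

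Alternatives set before the data were examined were DESeq2's size factors, DESeq2's tests, no filter on low counts, limma on log2 CPM, summed replicates, leaving out each replicate number or time point, the replicate number as a block, no trend, periods of 20 h and 28 h, leaving out 4 h and 8 h, a test against 2-fold, and fits of the compared groups alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.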

Results

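Transcript counts were measured by CEL-Seq in cells of a human embryonic stem cell line at 3 stages. Undifferentiated cells (D0) gave 3 libraries at 48 h. Cells after 15 and 30 days of differentiation towards cardiomyocytes (D15 and D30) gave 36 libraries each, triplicates every 4 h from 4 h to 48 h after dexamethasone. Median totals per library were 1202380 counts at D0, 356138 at D15 and 447579 at D30, with 10605 to 14707 genes detected. At D0 a single gene, PTMA (chromatin-associated prothymosin alpha), took 10.4% to 13.7% of the counts. The top gene of a library took at most 1.91% at D15 and 2.48% at D30. The design asks which genes follow a daily rhythm at D15 and D30, how the courses drift and how the stages differ.

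The first question was how D15 cells differed from D0 cells at 48 h, where stage and library preparation coincide. Contractile genes that were close to absent at D0 stood among the most abundant transcripts at D15. MYH6 and MYL7, the atrial myosin heavy and light chains, rose by 11.73 ± 0.85 and 11.73 ± 0.63 on the log2 scale. They went from 0.973 ± 1.69 and 1.33 ± 1.48 CPM to 4700 ± 2050 and 5700 ± 373 CPM (SD, n = 3 libraries per day). SOX2, a transcription factor that maintains pluripotency, stood at 792 ± 32.4 CPM at D0 against a single count at D15, a ratio of 0.000994 (95% counting interval 2.51e-05 to 0.00554). Of 8287 genes tested, 4420 were called, 2139 higher and 2281 lower at D15, and 3710 of them by more than 2-fold.

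All 14 tested sarcomere genes rose at D15, with a median log2 fold change of 7.67 (camera adjusted p = 8.45e-42; adjusted p = 0.00101 with an estimated correlation). Slow skeletal troponin I, TNNI1, which the fetal heart expresses, was 3990-fold higher (1100 to 33000), and MYBPC3, the cardiac myosin binding protein, 4480-fold higher (803 to 177000) against 1 count at D0. Among fetal cardiomyocyte genes 5 of 7 rose (median 10.6; adjusted p = 1.61e-17; adjusted p = 0.00101 with an estimated correlation). All 7 genes raised in mature cardiomyocytes rose (median 4.83; adjusted p = 8.59e-09; adjusted p = 0.0394 with an estimated correlation). CKM, muscle creatine kinase, rose by 8.02 ± 0.8, and MB, the oxygen store myoglobin, by 6.48 ± 0.95. Cardiac transcription factors rose in 3 of 4 cases (median 4.33; adjusted p = 0.00821; adjusted p = 0.0907 with an estimated correlation). Ratios were 114 (19.4 to 4580) for MEF2C and 75 (12.5 to 3060) for GATA4. Without D15 replicate 2 the list was not called (adjusted p = 0.0588). Of 13 genes of calcium handling and ion channels, 10 rose and 1 fell (median 2.57; adjusted p = 0.0033; adjusted p = 0.0557 with an estimated correlation). The sodium-calcium exchanger SLC8A1 was 141-fold higher (38.3 to 1180) and JPH2, which tethers the calcium store to the cell membrane, 181-fold (31.6 to 7260). The gap junction gene GJA1 fell by 4.04 ± 0.28. The other genes with the largest rises were ANKRD1, a stress-responsive muscle gene (4220-fold, 757 to 167000), the smooth muscle actin ACTA2 (10.56 ± 0.65) and the mesenchymal transcription factor FOXC1 (1110-fold, 199 to 44100). POPDC2 (8.78 ± 0.7), ALPK2 (689-fold, 123 to 27300) and CDKN2B, an inhibitor of cell cycle entry (641-fold, 114 to 25400), came next.

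Pluripotency genes fell in 15 of 16 cases (median -5.68, or -5.55 with the 2 genes at 0 counts set to their bound; camera adjusted p = 2.28e-17; adjusted p = 0.00342 with an estimated correlation). The stem cell transcript ESRG fell by 6.86 ± 0.49, and the NODAL co-receptor gene TDGF1 was at least 51.4-fold lower, with 0 counts at D15. LEFTY2, an inhibitor of NODAL that is also on the list, rose by 1.12 ± 0.3. Further genes at 0 counts at D15 were ALPL, the tissue-nonspecific alkaline phosphatase (at least 58.7-fold lower), MMP25 (54.2), SOX3 (53.6) and GNG4 (53.2). STEAP3 (46.6), ETV4 (44.5), MAL2 (29.9) and SKA3 (29.9) were at 0 counts too. All 23 cell cycle genes fell (median -3.11; adjusted p = 3.89e-16; adjusted p = 0.00738 with an estimated correlation). The mitotic kinase gene AURKB went from 2160 ± 630 to 145 ± 67.6 CPM, a log2 change of -3.75 ± 0.28. MCM5, part of the replicative helicase, fell by 3.48 ± 0.28. Ribosomal protein genes fell in 17 of 24 cases, or 19 adjusted over the list alone (median -0.87; adjusted p = 0.000134; adjusted p = 0.106 with an estimated correlation). RPS24 (-2.10 ± 0.23) and RPSA (-1.93 ± 0.22) were among them.

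Markers of other cell types also rose at D15. Fibroblast and matrix genes rose in 8 of 9 cases (median 5.77; adjusted p = 3.45e-13; adjusted p = 0.00738 with an estimated correlation). Fibronectin, FN1, went from 31 ± 14.8 to 3020 ± 1220 CPM (6.73 ± 0.31) and the collagen COL1A1 from 103 ± 22.9 to 5230 ± 1680 CPM (5.77 ± 0.26). In contrast THY1, a surface marker of fibroblasts and of stem cells, fell by 3.00 ± 0.27. All 7 smooth muscle genes rose (median 5.80; adjusted p = 4.95e-14; adjusted p = 0.00597 with an estimated correlation). TAGLN rose by 4.54 ± 0.27. Endoderm genes rose in 5 of 6 cases (median 4.24; adjusted p = 0.000125; adjusted p = 0.017 with an estimated correlation). The plasma carriers TTR and APOA1 rose by 6.15 ± 0.67 and 3.92. Of the 2 endothelial genes tested ENG rose by 3.27, and the 1 epicardial gene, KRT19, was not called (-0.31 ± 0.25, adjusted p = 0.314). Epithelial and neural lists moved both ways. KRT8 (2.85 ± 0.23) and KRT18 (2.73 ± 0.22) rose while EPCAM fell (-4.66 ± 0.49) and the splicing factor ESRP1 was at a ratio of 0.012 (0.000302 to 0.0675). Of 7 epithelial genes 3 rose and 4 fell (median -2.64; adjusted p = 0.726). Neural adhesion gene NCAM1 (3.50 ± 0.31) and MAP2 (3.81 ± 0.66) rose, and GAP43 (-3.85 ± 0.59) and SYT1 (-2.54 ± 0.68) fell. Of 8 neural genes 3 rose and 2 fell, with a median of 1.26 (adjusted p = 0.362 by camera and 0.00358 by fry).

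Metabolic and stress lists held genes that moved both ways. Fry, which compares a list with no other genes, called heat shock (adjusted p = 1.67e-05), oxidative phosphorylation (0.00178), fatty acid oxidation (0.00212) and oxidative stress (0.0192) among those that follow, and camera heat shock alone. Fatty acid oxidation had 5 of 17 genes up and 1 down (median 0.39; adjusted p = 0.371). FABP3, the heart fatty acid carrier (2.63 ± 0.26), and ETFB (1.35 ± 0.23) rose and ACAA2 fell (-1.73 ± 0.24). Oxidative phosphorylation had 3 of 28 up and 6 down (median -0.14; adjusted p = 0.508). NDUFV1 (1.07) and SDHA (0.89) rose and COX7C (-1.73 ± 0.25) and CYCS (-1.59 ± 0.25) fell. Glycolysis had 4 of 17 up and 3 down (median 0.11; adjusted p = 0.746). PFKP rose by 2.72 ± 0.25 and ALDOA by 0.90, and the glucose transporter SLC2A3 (-1.11 ± 0.23) and ALDOC (-0.99) fell. In the heat shock and unfolded protein list 2 rose and 11 fell of 19, or 3 and 12 adjusted over the list alone (median -0.74; adjusted p = 0.0366; adjusted p = 0.0907 with an estimated correlation). The chaperones HSPB1 (2.38 ± 0.21) and HSPA5 (0.64 ± 0.23) rose, and HSPE1 (-3.41 ± 0.28) and HSP90AB1 (-2.14 ± 0.21) fell. This list was not called with a GC offset per library (adjusted p = 0.064) or in a fit of D0 and D15 alone (0.122). Oxidative stress genes rose in 1 and fell in 5 of 18 cases (median -0.15; adjusted p = 0.546). NQO1 rose by 1.12 ± 0.23, and TXN (-2.23 ± 0.34) and HMOX1 (-2.89 ± 0.53) fell. Of 15 glucocorticoid-responsive genes 5 rose and 5 fell (median -0.35; adjusted p = 0.772). TXNIP was 64.5-fold higher (21.3 to 319) and CDKN1C rose by 1.84 ± 0.27. The metallothioneins MT1X (-6.35 ± 0.49) and MT2A (-3.06 ± 0.44) fell. In the core clock list 1 of 8 rose, the kinase CSNK1D (0.92 ± 0.24), and 1 fell, TIMELESS (-1.90 ± 0.37). Its median was 0.10, or -0.0557 with the GC offset, and its mean -0.16 (adjusted p = 0.963). Except where given, counts adjusted over the list alone equalled those over all genes. A test against a 2-fold change called 2143 genes.

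The same question was asked of D30 cells. Most tested sarcomere genes stood far above D0. TNNI1 was 3670-fold higher than at D0 (1020 to 30300) and MYL7 rose by 10.66 ± 0.63. H19, an imprinted transcript of fetal tissues, rose by 10.32 ± 0.44. The genes with the largest falls were at 0 counts at D30: the Notch ligase gene DTX2 (at least 381-fold lower), the mitochondrial ribosomal gene MRPL12 (259), RAB17 (226), the cytokine MIF (187) and VRTN (186). SLC25A29 (171), the phosphatase subunit PPP1CA (120), CAMKV (113), MVD (109) and HAPLN3 (96) were at 0 counts too. Of the 8287 genes, 6300 were called, 3167 higher and 3133 lower. Fold changes fell with the GC content of the transcript end (Spearman's rho across genes -0.58, against -0.021 for D15; genes are not independent replicates). With a GC offset per library, chosen after the data were seen, 5218 of 7788 genes were called and 189 genes called both ways had opposite directions.

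At D30 the sarcomere list rose in 11 and fell in 1 of 14 cases (median 6.15; camera adjusted p = 1.96e-11; adjusted p = 0.00816 with an estimated correlation). The gene that fell, cardiac troponin I, TNNI3, stood at -2.78 ± 0.62 as counted and at -0.29 (adjusted p = 0.685) with the GC offset. Fetal genes rose in 6 of 7 cases (median 7.37; adjusted p = 6.7e-07; adjusted p = 0.00816 with an estimated correlation). All 4 cardiac transcription factors rose (median 5.52; adjusted p = 0.000878; adjusted p = 0.109 with an estimated correlation). GATA4 was 748-fold higher (133 to 29600) and IRX4 rose by 5.05 ± 0.49. Of 13 calcium and channel genes 12 rose (median 4.39; adjusted p = 1.68e-05; adjusted p = 0.0577 with an estimated correlation). SLC8A1 was 306-fold higher (83.9 to 2540), the calcium pump gene ATP2A2 rose by 3.53 ± 0.24, and GJA1 fell (-1.47 ± 0.23). The mature list rose in 6 of 7 cases (median 4.19; adjusted p = 0.00734; adjusted p = 0.224 with an estimated correlation), CKM by 6.38 ± 0.8. With the GC offset its median was 7.14 (adjusted p = 2.14e-07; adjusted p = 0.063 with an estimated correlation). Pluripotency genes fell in 14 of 16 cases (median -5.46; adjusted p = 1.73e-07; adjusted p = 0.00816 with an estimated correlation). LIN28A (-7.30 ± 0.5) and ESRG (-7.81 ± 0.62) fell and LEFTY2 rose (2.83 ± 0.29). Cell cycle genes fell in 21 of 23 cases (median -2.17; adjusted p = 6.7e-07; adjusted p = 0.00816 with an estimated correlation). MCM5 fell to -7.10 ± 0.59 and AURKB to -5.32 ± 0.31.

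Fibroblast genes rose in 7 and fell in 1 of 9 cases at D30 (median 5.52; adjusted p = 6.05e-05; adjusted p = 0.0613 with an estimated correlation). COL1A2 rose by 6.96 ± 0.3 and COL1A1 by 5.72 ± 0.26, and THY1 fell (-2.69). Smooth muscle genes rose in 5 of 7 cases (median 3.56; adjusted p = 0.0131; adjusted p = 0.207 with an estimated correlation). ACTA2 rose by 9.64 ± 0.65, and MYOCD, a co-activator of smooth muscle genes, was at a ratio of 114 (19.5 to 4580). As counted, all 7 epithelial genes fell (median -2.94; adjusted p = 0.00734; adjusted p = 0.131 with an estimated correlation), and with the GC offset 5 fell and 1 rose. KRT18 (-3.68 ± 0.27) and EPCAM (-2.79 ± 0.32) were among them. Neural genes rose in 4 and fell in 1 of 8 cases (median 1.94, or 1.06 with the GC offset; adjusted p = 0.144). PAX6, a regulator of forebrain and eye development, was 558-fold higher (99.3 to 22100) against 1 count at D0. NES was at a ratio of 0.00675 (0.000816 to 0.0245). Both endothelial genes fell to 0 counts, EGFL7 at least 20-fold and ENG at least 3.29-fold lower, ENG with no call under the GC offset (adjusted p = 0.107). KRT19 of the epicardial list fell by 2.60 ± 0.28 (-0.39, adjusted p = 0.201, with the GC offset). Endoderm genes rose in 3 and fell in 2 of 6 cases, with a median of 0.54 and a mean of -0.51 (adjusted p = 0.998). With the GC offset 2 rose and 2 fell (median -1.09). TTR rose by 7.45 ± 0.66 and AFP by 1.98 ± 0.59 (-0.01 with the GC offset), while APOE was at a ratio of 0.00292 (0.000353 to 0.0106) and APOA1 at least 3.73-fold lower (adjusted p = 0.207 with the GC offset). The other largest rises were GAS1 (1860-fold, 333 to 73500), the matrix gene CTHRC1 (1260-fold, 226 to 50000) and KCTD12 (1220-fold, 338 to 10100). ALPK2 (942-fold, 168 to 37300), SLIT3 (891-fold, 159 to 35300) and the chemokine CXCL14 (755-fold, 258 to 3670) came next.

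Members of the same list moved both ways at D30. Of 28 oxidative phosphorylation genes 10 rose and 13 fell (median -0.37, or -0.533 with the GC offset; adjusted p = 0.807). ATP5J (3.77 ± 0.22) and UQCRB (3.79 ± 0.26) rose, NDUFV1 fell (-5.47 ± 0.73) and NDUFA13 was at a ratio of 0.00533 (0.000644 to 0.0193). Ribosomal protein genes rose in 2 and fell in 17 of 24 cases (median -1.64; adjusted p = 2.18e-05; adjusted p = 0.109 with an estimated correlation). They ran from RPL30 (1.54) and RPL5 (0.50; adjusted p = 0.0914 with the GC offset) to RPS14 (-4.64 ± 0.24) and RPSA (-4.85 ± 0.25), with an SD of 1.71 across the list against 0.604 at D15. Glycolysis genes rose in 4 and fell in 11 of 17 cases (median -1.14, or 0.179 with the GC offset; adjusted p = 0.0699). PKM rose by 1.23 and LDHA by 1.17 (0.53, adjusted p = 0.0775, with the GC offset), and ENO1 (-3.66 ± 0.25) and SLC2A3 (-3.94) fell. Fatty acid oxidation genes rose in 8 and fell in 5 of 17 cases, with a median of -0.22 and a mean of 0.29 (adjusted p = 0.759; median 0.522 with the GC offset). FABP3 rose by 3.06 ± 0.25 and HADHB by 2.08, ACAA2 fell by 2.73, and ECI1 moved from -1.67 to 0.02 with the GC offset. CACNA1H, a calcium channel gene, moved from -1.75 to 0.62. Heat shock genes rose in 5 and fell in 12 of 19 cases (median -1.23; adjusted p = 0.0641). HERPUD1 rose by 3.53 and HSPA1B by 3.44, ATF4 fell (-4.58 ± 0.24) and TRIB3 was at least 43.6-fold lower. Oxidative stress genes rose in 6 and fell in 8 of 18 cases (median -0.13, or -0.283 with the GC offset; adjusted p = 0.537). TXN rose by 2.60 and PRDX3 by 2.35 (0.50, adjusted p = 0.116, with the GC offset), and GPX1 (-4.28) and GPX4 (-4.66) fell. Of 15 glucocorticoid-responsive genes 8 rose and 5 fell (median 1.26; adjusted p = 0.684), and with the GC offset 5 rose and 4 fell (median 0.303). TXNIP was 427-fold higher (145 to 2080), CDKN1C rose by 3.41 ± 0.26, and MT1X was at a ratio of 0.00152 (0.000184 to 0.00549) and MT1E at 0.0127 (0.00261 to 0.0373). As counted, all 8 core clock genes were called, 4 up and 4 down, and 2 up and 2 down with the GC offset. The list as counted had a median of -0.33 and a mean of 0.13 (adjusted p = 0.998). CLOCK rose by 2.14 ± 0.32 (0.59, adjusted p = 0.0844, with the GC offset), and CSNK1E (-1.79 ± 0.25) and TIMELESS (-2.68 ± 0.43) fell. Stage and library preparation cannot be separated in this comparison or that of D15, since each day was sequenced as its own library.

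**Figure D1:**
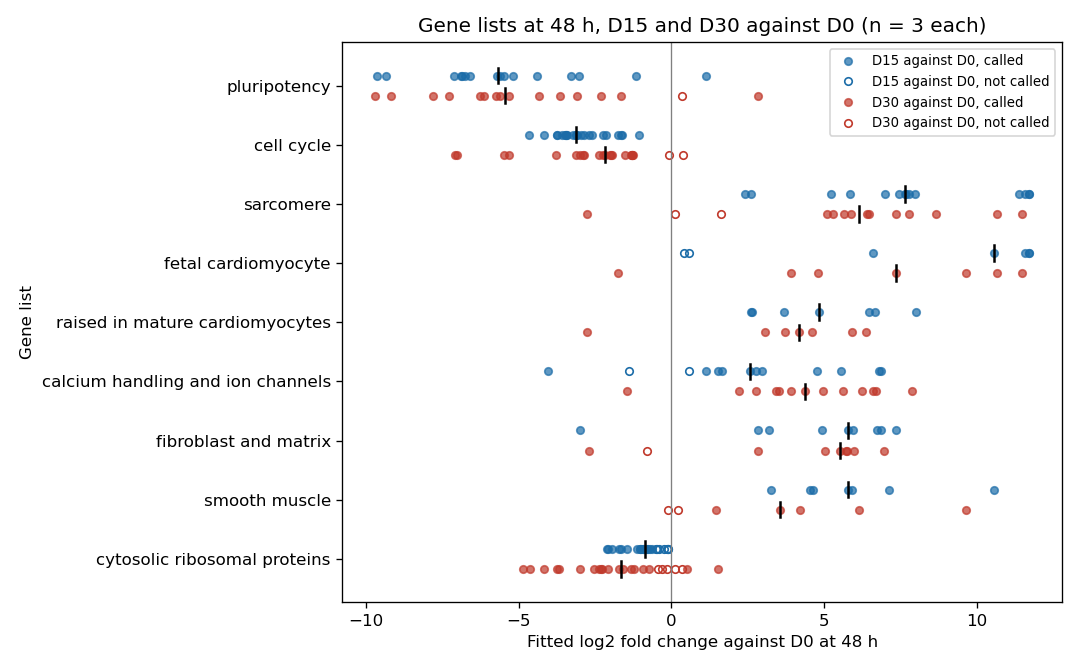
Fitted log2 fold change against D0 at 48 h (x axis) of the tested genes of 9 lists (y axis) at D15 (blue) and D30 (red), with 3 libraries per day; filled points were called, open points were not, black bars are medians, and fitted values of genes at or near 0 counts in a group depend on the prior count. Sarcomere genes lie to the right at both days (medians 7.67 and 6.15) and pluripotency genes to the left (-5.68 and -5.46), while ribosomal protein genes spread over an SD of 0.604 at D15 and 1.71 at D30.

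Between D30 and D15, compared over the 12 matched time points with 36 libraries each, nearly every tested gene differed. Among the largest rises, FEZF2, a transcription factor of the forebrain, went from 0.424 to 186 ± 104 CPM (7.96 ± 0.75), and ELN, the gene of elastin, rose by 7.78 ± 0.94. PAX6 (6.73 ± 0.46) and SOX2 (6.10 ± 0.38) rose as well. The largest falls were in MIF, at 395 ± 136 CPM at D15 against 1 count at D30 (ratio 0.000138, 3.5e-06 to 0.000771), and in APOE, a lipid carrier (-8.93 ± 0.34, or -4.19 with the GC offset). Of 6956 genes, 6467 (93%) were called, 3125 higher and 3342 lower at D30, and 4624 by more than 2-fold. Again the fold changes followed GC content (rho across genes -0.6). With the GC offset 5959 of 6564 genes (90.8%) were called, and 837 genes called both ways had opposite directions. The median over all genes was -0.08 with TMM and 0.12 with DESeq2's size factors, so changes of that size have no fixed direction. The share of counts in MTRNR2L genes, nuclear copies of a mitochondrial sequence, moved with the day as well, with medians of 0.302% at D0, 0.792% at D15 and 2.18% at D30.

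**Figure D2:**
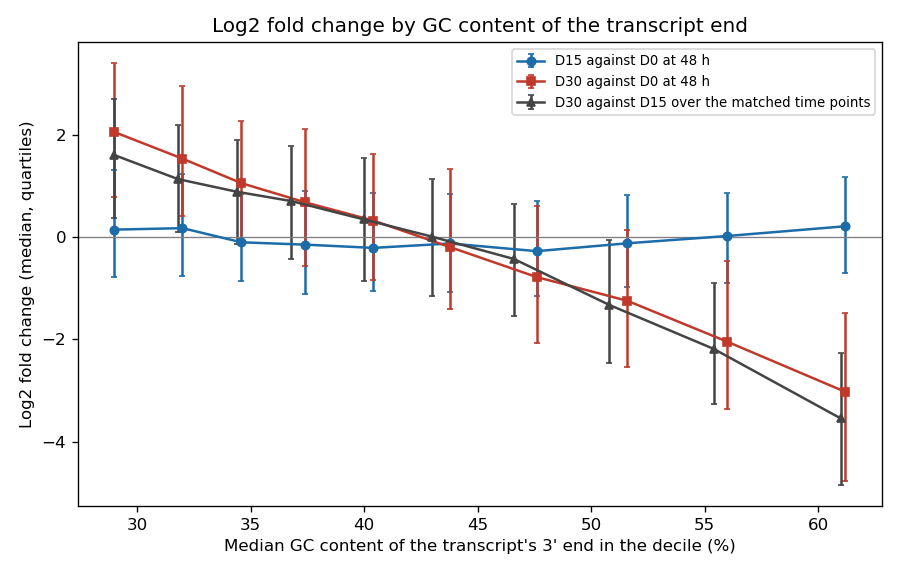
Median log2 fold change (y axis; bars are quartiles) of genes in 10 groups by GC content of the last 500 bases of their transcript (x axis, %) for the 3 comparisons between days. The medians fall with GC content for D30 against D0 and for D30 against D15 (rho -0.58 and -0.6) and stay near 0 for D15 against D0 (-0.021).

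Most tested genes of the calcium list stood higher at D30 and most of smooth muscle lower, and camera called neither list. In the calcium list 12 of 13 genes rose and 1 fell (median 1.77, or 1.08 with the GC offset; camera adjusted p = 0.0992; adjusted p = 0.751 with an estimated correlation). PLN, the regulator of the calcium pump, rose by 3.00 ± 0.078 and GJA1 by 2.10 ± 0.09. JPH2 stood at -1.58 as counted and 0.35 with the GC offset. As counted, all 8 smooth muscle genes fell (median -1.76; camera adjusted p = 0.101; adjusted p = 0.898 with an estimated correlation), and with the GC offset 6 fell and 1 rose (median -1.65). TAGLN stood at -4.57 ± 0.1 and CNN1 at -4.32 ± 0.12. Sarcomere genes rose in 5 and fell in 18 of 23 cases (median -0.72; adjusted p = 0.383), and with the GC offset 6 rose and 12 fell (median -0.183). SMPX (3.16 ± 0.1) and MYOZ2 (2.70 ± 0.096) rose, and MYH6 (-4.65 ± 0.097) and MYBPC3 (-2.57 ± 0.089, or -0.19 with the GC offset) fell. Cardiac transcription factors rose in 7 and fell in 2 of 10 cases (median 1.34; adjusted p = 0.274). HAND2 rose by 3.65 ± 0.1 and GATA4 by 2.61 ± 0.12, ISL1 fell (-1.36 ± 0.15) and NKX2-5 stood at -1.60 ± 0.15 as counted but 1.49 with the GC offset. Of 12 mature genes 6 rose and 6 fell (median -0.01, within the shift between scalings, and 1.66 with the GC offset; adjusted p = 0.748). CASQ2 rose (1.98 ± 0.12), TNNI3 fell (-3.84 ± 0.16) and MYH7, the slow myosin heavy chain, stood at -2.61 ± 0.11 as counted but 0.12 with the GC offset. Fetal genes fell in 9 of 10 cases (median -1.59, or 0.169 with the GC offset; adjusted p = 0.396). MYL4 stood at -2.07 (-0.03 with the GC offset), and the pacemaker channel HCN4 rose (2.19 ± 0.19).

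Fibroblast genes rose in 6 and fell in 8 of 14 cases, with a median of -0.67 and a mean of 0.41 (adjusted p = 0.971). With the GC offset 6 rose and 6 fell (median 0.125). COL6A3 (4.21 ± 0.24) and COL3A1 (1.65 ± 0.092) rose, and PDGFRB (-3.86 ± 0.14) and FN1 (-2.25 ± 0.096) fell. Neural genes rose in 4 and fell in 1 of 6 cases (median 2.32; adjusted p = 0.715). GAP43 rose by 4.03 ± 0.19 and NES fell (-6.48 ± 0.15). Endoderm genes rose in 1 and fell in 5 of 6 cases (median -2.91; adjusted p = 0.101). TTR rose by 0.85 ± 0.16 and APOA1 was at a ratio of 0.000877 (0.000106 to 0.00317). Epithelial genes rose in 1 and fell in 3 of 4 cases (median -3.58, or -1.31 with the GC offset; adjusted p = 0.101). EPCAM rose by 2.54 ± 0.19, and KRT18 (-6.17 ± 0.082) and KRT8 (-3.57 ± 0.075) fell. ENG, the 1 endothelial gene, was at a ratio of 0.000773 (1.95e-05 to 0.00431), and KRT19, the 1 epicardial gene, fell by 2.87 (-0.40 with the GC offset). Pluripotency genes rose in 3 and fell in 2 of 5 cases (median 0.71, or -0.568 with 2 up and 3 down with the GC offset; adjusted p = 0.744). LEFTY2 (2.03 ± 0.1) rose beside SOX2, and L1TD1 (-3.66 ± 0.17) and LIN28A (-1.69 ± 0.2) fell. Cell cycle genes rose in 9 and fell in 10 of 21 cases (median -0.21; adjusted p = 0.971). PCNA (2.83 ± 0.11) and UBE2C (2.24 ± 0.13) rose, and MCM5 (-3.35 ± 0.16) and TPX2 (-2.12 ± 0.098) fell.

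Members of one complex or pathway parted between D15 and D30. Ribosomal protein genes rose in 7 and fell in 15 of 24 cases (median -0.61; adjusted p = 0.129). RPL30 rose by 2.97 ± 0.066 and RPS24 by 1.99, and RPS14 (-3.87 ± 0.06) and RPS19 (-3.49 ± 0.061) fell. Oxidative phosphorylation genes rose in 11 and fell in 15 of 28 cases, with a median of -0.34 and a mean of 0.06 (adjusted p = 0.715). With the GC offset 10 of 22 rose and 10 fell (median 0.0998). ATP5J (4.21 ± 0.062) and UQCRB (3.51 ± 0.072) rose, and NDUFA13 (-7.10 ± 0.18) and NDUFV1 (-7.16 ± 0.26) fell. Glycolysis genes rose in 5 and fell in 11 of 17 cases (median -1.08, or 0.543 with the GC offset; adjusted p = 0.43). PKM rose by 1.64 and LDHA by 1.51, SLC2A3 fell (-2.68), and PFKL stood at -3.44 as counted but 0.75 with the GC offset. Fatty acid oxidation had 7 up and 8 down of 16 (median -0.29, or -0.14 with the GC offset; adjusted p = 0.748). ETFA (1.89) and HADHB (1.48) rose and ECI1 (-2.87) and ETFB (-2.80, or -0.03 with the GC offset) fell. Oxidative stress had 6 up and 9 down of 16 (median -0.42, or 0.198 with 8 up and 7 down with the GC offset; adjusted p = 0.954). TXN (4.87) and PRDX3 (4.36) rose and GPX1 (-3.94) and GPX4 (-5.38) fell. Heat shock had 7 up and 10 down of 18 (median -0.45; adjusted p = 0.744). HSPA1B (4.88) and HSPE1 (2.83) rose and CALR (-2.98) and HSPA5 (-2.61) fell. Glucocorticoid-responsive genes rose in 5 and fell in 3 of 8 cases (median 0.62; adjusted p = 0.715). TXNIP rose by 1.84 and CEBPB by 1.45, and TSC22D3 (-0.65) and GLUL (-0.54) fell. In the core clock list 4 of 7 rose and 3 fell (median 0.59, or -0.203 with 2 up and 3 down with the GC offset; adjusted p = 0.971). CLOCK rose by 1.36 ± 0.097, and CSNK1D (-2.80 ± 0.076) and CSNK1E (-1.98 ± 0.078) fell. Camera called 0 of the 20 lists tested, with 5 at an unadjusted p under 0.05. Camera on DESeq2's statistics called 1, without the filter 2, and on the 48 h libraries alone 7. Fry, which compares a list with no other genes, called 19 of the 20, all but the fibroblast list (adjusted p = 0.125), so it sets no list apart. The other named rises were OGN (673-fold, 186 to 5560), GAS1 (7.60 ± 0.31), CRABP1 (507-fold, 140 to 4190) and SULT1E1 (7.28 ± 0.97). LOC728554 (361-fold, 123 to 1750), HOXB2 (7.12 ± 0.61), TYRP1 (6.84 ± 0.72) and ZIC2 (6.84 ± 0.82) followed. The other named falls were DAPK3 (-9.36 ± 0.52, or -5.68 with the GC offset), INTS1 (ratio 0.000249, 6.3e-06 to 0.00139) and MRPL12 (-9.07 ± 0.53). MRPL28 (-8.33 ± 0.49), SGTA (-8.24), C19orf70 (-8.11) and MVD (-7.90 ± 0.33) followed. Day and sequencing library coincide, so no value within a batch can be given.

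Whether D15 cells kept daily time after the pulse was asked of 7274 genes with the 24-h test. SPON2 and LUM, both secreted matrix proteins, had the smallest p, with peak-to-trough differences of 7.81 ± 1.28 and 5.25 ± 0.922 (adjusted p = 1.37e-07 and 1.58e-05; peaks at 20.8 and 20.5 h). Much of the SPON2 difference and most of that of LUM rested on 1 library, replicate 3 of 20 h, with 3610 CPM of SPON2 and 3221 CPM of LUM against means of 133 and 122 CPM over the 36 libraries. TUBB4B, a tubulin, and KIF4A, a mitotic kinesin, peaked at 7.3 and 7.1 h with differences of 1.11 ± 0.176 and 1.81 ± 0.325 (adjusted p = 0.00123 and 0.00266). In all 89 genes were called, against 979 at an unadjusted p under 0.05 where 364 would be met by chance. Without replicate 3 of 20 h 16 were called by edgeR, and with each other library left out 42 to 125. Those that moved the count by over 1.5 times were replicates 2 and 1 of 20 h (42 and 49), 2 of 32 h (49), 1 of 8 h (57) and 3 of 36 h (57). The first 24 h alone gave 19 genes, 15 of them among the 89, and the last 24 h alone 3, with 0 among the 89.

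Fibroblast and matrix genes were called in 4 of 11 cases, COL1A2, COL5A1, LUM and THY1, or 8 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000142). COL5A1, a fibrillar collagen gene, had a difference of 1.08 ± 0.194 with a peak at 21.5 h. Cell cycle genes were called in 3 of 19 cases, or 13 adjusted over the list alone (adjusted p = 0.0109). They were the kinetochore gene CENPF (1.07 ± 0.215, peak 9.44 h), AURKB (1.29 ± 0.261, peak 7.01 h) and CDC20. Glucocorticoid-responsive genes were called in 3 of 13 cases, or 4 adjusted over the list alone (adjusted p = 0.0051). They were the cell cycle inhibitor CDKN1C (1.3 ± 0.343, peak 19.9 h), MT1E (1.72 ± 0.369, peak 0.502 h) and MT2A. Endoderm genes were called in 2 of 7 cases, or 4 adjusted over the list alone (adjusted p = 0.0164), APOA1 with a peak at 9.39 h and AFP at 9.06 h. These 4 lists were called, and DESeq2's likelihood ratio test called 2 lists, limma 0. A permutation of the time points on the list means, chosen after the data were seen, called none of them (adjusted p = 0.141 for fibroblast, 0.193 for cell cycle, 0.941 for glucocorticoid-responsive and 0.498 for endoderm genes; unadjusted p = 0.00675, 0.0224, 0.718 and 0.0926). Single members were called of the epithelial (KRT7, of 3), fetal (ACTA1, of 9), fatty acid oxidation (CPT1A, of 17) and heat shock lists (HSPA8, of 19), with adjusted p from 0.16 to 0.574 for the lists. The other genes of smallest p were TGFBI (4.18 ± 0.714), NNMT (4.33 ± 0.775), AQP1 (2.44 ± 0.464), DLK1 (3.11 ± 0.688) and SLC9A3R1 (1.79 ± 0.392), all with a fitted peak between 19.6 and 20.7 h. Without replicate 3 of 20 h, an omission chosen after the data were seen, none of these 5 was called, with differences of 1.46, 1.94, 0.59, 0.97 and 0.46 in that order, nor were LUM (1.59), CDKN1C (0.19), APOA1, AFP, ACTA1, CPT1A and HSPA8, and of the lists the cell cycle alone was called (4 genes, adjusted p = 1.28e-06; fibroblast 1 gene, adjusted p = 0.157). SPON2 (3.97), COL5A1 (0.78), TUBB4B (1.10), KIF4A (1.96), AURKB (1.52), CENPF (1.10), MT1E (1.75) and KRT7 (1.37) were still called. Without all of 20 h 0 lists were called, and TGFBI (0.98), NNMT (0.77), AQP1 (0.72), SLC9A3R1 (0.34), SPON2 (2.44) and COL5A1 (0.73) were not. CDKN1C ran from 0.06 without replicate 3 to 1.69 without replicate 1. At 20 h the mean of the fibroblast list stood 0.70 above the mean of the course, with the sarcomere (-0.51 ± 0.98), fetal (-0.77 ± 1.2) and smooth muscle (-0.75 ± 1) lists below it (SD, n = 3 libraries).

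No core clock gene was called at D15 by edgeR. Of 7 tested, 0 passed over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and DESeq2 and limma called 0 as well. CRY2, a repressor of the clock, came closest (0.66 ± 0.315, adjusted p = 0.519). The peak-to-trough differences of the others were 0.56 for TIMELESS, 0.64 for NFIL3, 0.38 for PER1, 0.33 for CLOCK, 0.09 for CSNK1E and 0.06 for CSNK1D. CLOCK and its partner ARNTL drive PER2, PER3, NR1D1 and DBP, which swing over the day in many tissues. ARNTL stood at 1.41 CPM, PER2 at 3.08, PER3 at 1.71, NR1D1 at 0.289 and DBP at 3.76. None of them passed the filter. Tested without it, 0 of 24 clock genes were called by edgeR, with 4 at an unadjusted p under 0.05, and the adjusted p was 0.77 for ARNTL, 1 for PER2, 0.593 for PER3, 0.176 for NR1D1 and 0.982 for DBP. Further lists with 0 members called, each followed by the number at an unadjusted p under 0.05, were sarcomere (24 genes, 5), oxidative phosphorylation (26, 4), ribosomal proteins (24, 0), glycolysis (16, 1), oxidative stress (14, 2), mature genes (12, 1) and calcium (11, 1). The same held for smooth muscle (8, 1), cardiac transcription factors (7, 2), pluripotency (6, 2), neural (4, 1), endothelial (2, 2) and epicardial genes (2, 2). Adjusted over the list alone 1 smooth muscle, 1 pluripotency, 1 neural, 2 endothelial and 2 epicardial genes passed.

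The same test was run on the D30 course. PFKFB3 and HK2, which drive glycolysis, had peak-to-trough differences of 1.93 ± 0.256 and 1.54 ± 0.237 (adjusted p = 1.38e-05 and 0.000323), PFKFB3 with a peak at 17.1 h. BNIP3, a mitophagy receptor induced in hypoxia, followed with 1.53 ± 0.204 at 19.1 h (adjusted p = 1.38e-05). It went from 248 ± 21.1 CPM at 8 h to 990 ± 322 CPM at 20 h and 682 ± 135 CPM at 44 h (SD, n = 3 libraries). C1orf51, also named CIART, a repressor in the clock, peaked at 18.3 h with 1.96 ± 0.367 (adjusted p = 0.00265). It was counted 210 times in 35 of 36 libraries, with 3.9 ± 3.39 CPM at 4 h and 25.8 ± 15.5 CPM at 20 h. Of 8068 genes 73 were called, with 869 at an unadjusted p under 0.05 against 403 for independent libraries. The first 24 h alone called 84 genes, 30 of them among the 73, and the last 24 h alone 6, with 3 among the 73. Limma called 33. With the means of the fibroblast and neural lists as covariates, chosen after the data were seen, 11 were called, PFKFB3, BNIP3 and HK2 among them and C1orf51 not.

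**Figure D3:**
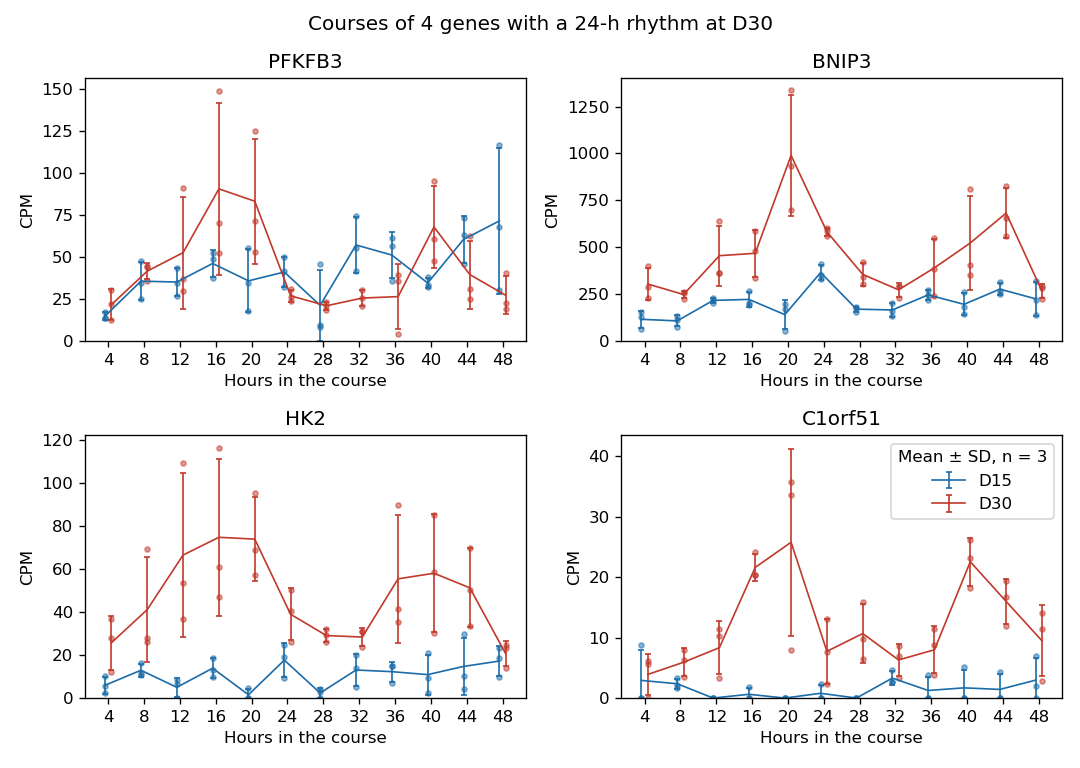
Expression in CPM (y axis) against hours in the course (x axis) of PFKFB3, BNIP3, HK2 and C1orf51 at D15 (blue) and D30 (red); small points are libraries, lines join the means and bars are the SD of 3 libraries. At D30 BNIP3 reaches 990 ± 322 CPM at 20 h and 682 ± 135 CPM at 44 h, and C1orf51 25.8 ± 15.5 CPM at 20 h and 22.5 ± 3.97 CPM at 40 h.

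The core clock list had 1 of 10 genes called at D30, 2 adjusted over the list alone and 3 at an unadjusted p under 0.05. Beside C1orf51, the transcriptional repressors BHLHE40 (1.32 ± 0.41, peak 17.4 h, adjusted p = 0.171, or 0.0344 without the filter) and NFIL3 (0.63, adjusted p = 0.422) came closest. CLOCK (0.25), CRY1 (0.20), CSNK1D, CSNK1E, TIMELESS and CRY2 were not called. The low clock genes were again under the filter, ARNTL at 7.3 CPM, PER2 at 3.92, PER1 at 7.53, NR1D1 at 0.501 and DBP at 0.245. Tested without the filter none of these 5 was called (adjusted p = 0.58, 0.39, 0.811, 0.6 and 0.245 in that order).

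Fibroblast and matrix genes were called in 4 of 14 cases at D30, COL5A1, COL6A3, DCN and LUM, or 11 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000127). DCN had a difference of 1.26 at 19.1 h and COL5A1 of 0.82 at 20.6 h. Smooth muscle genes were called in 3 of 7 cases, or 4 adjusted over the list alone (adjusted p = 0.000267). ACTA2 (0.77 ± 0.145, peak 17 h) and MYLK (1.00, peak 17 h) were among them, and ACTA2 is also the 1 of 9 fetal genes called (adjusted p = 0.273). Glycolysis genes were called in 3 of 17 cases, HK2, SLC2A1 and SLC2A3, or 5 adjusted over the list alone (adjusted p = 0.00324). Glucocorticoid-responsive genes were called in 2 of 12 cases, CRISPLD2 (1.42, peak 22 h) and CDKN1C (0.62, peak 20 h), or 4 adjusted over the list alone (adjusted p = 0.0276). In the heat shock list the chaperones HSPA8 (0.60 ± 0.0873, peak 14.2 h) and HSP90AA1 (0.45, peak 14.9 h) were called of 18 (adjusted p = 0.0495). DESeq2's likelihood ratio test called 3 lists and limma 2. The permutation of the time points on the list means, chosen after the data were seen, called none of the 5 (adjusted p = 0.603 for fibroblast, 0.498 for smooth muscle, 0.894 for glycolysis, 0.894 for glucocorticoid-responsive and 0.941 for heat shock genes; unadjusted p from 0.0818 to 0.481). The remaining genes of smallest p were SBSPON (1.45 ± 0.208), TGFB2 (0.94 ± 0.153), LGALS1 (1.17 ± 0.2), STC2 (1.44 ± 0.25) and PLOD2 (1.03 ± 0.174), with peaks between 16.6 and 19 h. CPNE5 (1.20 ± 0.199) peaked at 3.89 h. Lists with 0 called, with the number at an unadjusted p under 0.05, were oxidative phosphorylation (26 genes, 2), ribosomal proteins (24, 1), sarcomere (22, 3), cell cycle (21, 3), fatty acid oxidation (18, 0) and calcium (17, 2). The same held for oxidative stress (16, 1), mature genes (13, 3), cardiac transcription factors (12, 0), pluripotency (8, 1), neural (8, 1), epithelial (4, 2), endoderm (3, 1), epicardial (3, 2) and endothelial genes (2, 1). Adjusted over the list alone 2 epicardial genes passed, and 1 each of the pluripotency, mature, oxidative phosphorylation, endothelial and epithelial lists. Leaving out a library moved the count of 73 to 31 (replicate 2 of 20 h), 38 (2 of 32 h), 41 (3 of 16 h), 42 (3 of 20 h, 1 of 40 h), 48 (3 of 28 h) and 121 (1 of 28 h).

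**Figure D4:**
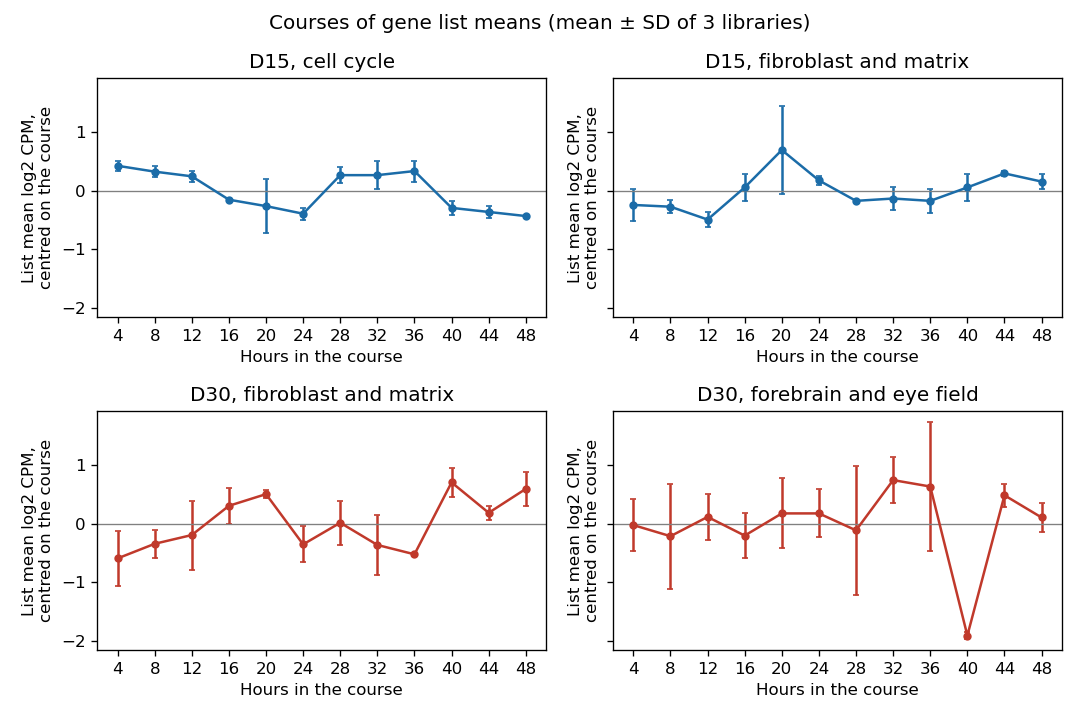
Mean log2 CPM of the genes of a list, centred on the mean of the day (y axis), against hours in the course (x axis) for cell cycle and fibroblast genes at D15 and fibroblast and forebrain genes at D30, the last list chosen after the data were seen; points are means and bars the SD of 3 libraries. Cell cycle genes at D15 run from 0.43 at 4 h to -0.39 at 24 h and 0.34 at 36 h, and forebrain genes at D30 drop to -1.91 at 40 h.

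Whether the rhythms differed between days was tested directly, since a gene called at one day alone shows no difference. Of 9960 genes 16 were called, with 796 at an unadjusted p under 0.05. They were led by FRZB, a Wnt antagonist (6.39 ± 1.08, adjusted p = 3.01e-07), NPY, neuropeptide Y (7.28 ± 1.25, adjusted p = 3.01e-07), and DCN, the matrix proteoglycan decorin (8.92 ± 1.84, adjusted p = 5.87e-07). Of the lists fibroblast genes had 2 of 14 called, DCN and LUM (Fisher's exact test, adjusted p = 0.00479). The cardiac transcription factors had HAND1 of 12 and the neural list STMN2 of 9 (adjusted p = 0.14 for each list). In the core clock list 0 of 12 were called by edgeR, with 2 at an unadjusted p under 0.05. These were C1orf51 (3.48 ± 1.02, adjusted p = 0.168) and ARNTL2 (adjusted p = 0.28), and both passed adjusted over the list alone. C1orf51 held 29 counts in 14 of 36 D15 libraries and ARNTL2 122 counts in 28, both under the filter of the D15 test. Adjusted over the list alone 8 of 24 cell cycle, 6 of 17 glycolysis, 3 of 8 smooth muscle and 2 of 20 heat shock genes passed, where 0 passed over all genes. The count fell to 0 without replicate 3 of 20 h at D15, where DCN stood at 624.6 CPM, and to 10 without replicate 2 of 20 h at D30. By limma 0 were called and by DESeq2's likelihood ratio test 9.

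Drift over the 48 h was asked with the linear trend. At D15 the BMP target genes ID3 and ID1, inhibitors of differentiation, rose by 2.14 ± 0.22 and 1.86 ± 0.24 over the course (adjusted p = 3.95e-09 for ID3). ID3 stood at 117 ± 29.9 CPM at 24 h and at 233 ± 38.4 CPM at 28 h. DSP, the desmosomal gene desmoplakin, fell by 1.65 ± 0.2. PTPRF (1.42 ± 0.17), the cyclin gene CCND2 (1.24 ± 0.15) and GLIS2 (1.78 ± 0.23) rose, and BCYRN1 (-2.10 ± 0.25), GOLGA2 (-1.37 ± 0.17) and the copper transporter SLC31A1 (-1.79 ± 0.22) fell. Of 7274 genes 1778 were called, 837 rising and 941 falling. With a step between 24 h and 28 h beside the trend, chosen after the data were seen, 16 were called. A mid-course step overlaps with a linear trend, so slopes beside it are less precise. The libraries of the first and last 24 h parted on the first principal component (18.2% of the variance), 17 of 18 below 0 in the first and 17 of 18 above 0 in the second.

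Among the lists at D15, ribosomal protein genes rose in 9 of 24 cases and fell in none (10 adjusted over the list alone). RPL13A rose by 1.00 and RPL10A by 1.12, the last turning to -0.76 beside the step (adjusted p = 0.638). Oxidative phosphorylation genes rose in 6 and fell in 2 of 26 cases (10 over the list alone), with ATP5A1 at 0.79 and COX5A at 0.92. Cell cycle genes fell in 6 and rose in 1 of 19 cases (7 over the list alone). TPX2 stood at -1.05 and MKI67 at -0.93 against AURKB at 0.83, which turned to -1.84 beside the step (adjusted p = 0.48). Heat shock genes rose in 5 of 19 cases, fatty acid oxidation genes in 4 of 17 with 1 falling (PPARA, -1.56) and glycolysis genes in 4 of 16 (PFKM, 1.14). Endoderm genes rose in 4 of 7 cases (AFP, 1.76; APOA2, 1.39; 5 over the list alone) and smooth muscle genes in 3 of 8 with 1 falling (5 over the list alone). Sarcomere genes rose in 3 of 24 (MYH7, 1.11; 2 over the list alone) and mature genes in 3 of 12 with 1 falling (5 over the list alone). Fibroblast genes rose in 2 and fell in 2 of 11 cases, PDGFRB by 1.80. Glucocorticoid-responsive genes rose in 2 of 13 cases, TXNIP by 1.38 and TSC22D3 by 0.78, and core clock genes in 2 of 7. Oxidative stress genes rose in 1 and fell in 2 of 14, and of 6 pluripotency genes LEFTY2 rose (2.03) and L1TD1 fell (-2.03). Both epicardial genes fell (UPK1B -1.75, KRT19 -1.61, the last turning to 0.67 beside the step, adjusted p = 0.92). DCX of the neural list rose by 2.20 and ACTA2 of the fetal list and ENG of the endothelial list rose. GJA1 of the calcium list and KRT7 of the epithelial list fell, and 0 of 7 cardiac transcription factors were called. By Fisher's exact test 0 lists held more called genes than the others (smallest adjusted p = 0.594). Without the filter on low counts 5 did: ribosomal proteins (adjusted p = 0.00526), fibroblast genes (0.00682), oxidative phosphorylation (0.0286), mature genes (0.0346) and smooth muscle (0.0346).

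At D30 the trend called 32 genes, 11 rising and 21 falling. TXNIP, a glucose-regulated inhibitor of thioredoxin, rose by 1.34 ± 0.19 (adjusted p = 2.94e-05), from 172 ± 39.2 CPM at 4 h to 442 ± 61.1 at 48 h, and LEFTY2 by 0.78 ± 0.13. ACTC1, cardiac actin, fell by 1.10 ± 0.16 (adjusted p = 2.94e-05), from 18000 ± 5410 to 6660 ± 480 CPM, and ACTA2 by 1.00. SHISA5 (0.75), YPEL3 (1.10) and IVNS1ABP (0.70) rose too, and PHB (-1.11), the nucleotide carrier SLC25A4 (-0.95) and CYC1 (-0.88) fell. Sarcomere genes fell in 2 of 22 cases, ACTC1 and TPM1 (-0.65), or 9 over the list alone. From 4 h to 48 h the mean of the sarcomere list went from 0.18 to -0.40 and that of the fibroblast list, with 0 genes called by edgeR and 5 at an unadjusted p under 0.05, from -0.59 to 0.60. Oxidative phosphorylation genes fell in 2 of 26 cases, CYC1 and CYCS (-0.52), or 4 over the list alone (Fisher's exact test, adjusted p = 0.0342 for each list). Heat shock genes fell in 2 of 18 cases, HSPA8 (-0.50) and HSPE1 (-0.46), or 3 over the list alone (same test, adjusted p = 0.0342). HSPA8 stood at 0.12 beside a step between 24 h and 28 h (adjusted p = 0.952). Without the filter, with the same limit, the sarcomere list was still called (adjusted p = 1.08e-05) and the fetal list as well (0.00324). Oxidative phosphorylation had 1 of 28 genes called (adjusted p = 0.258) and heat shock 0 of 20 by edgeR, 5 of them at an unadjusted p under 0.05. ACTA2 was the 1 gene called of 7 smooth muscle genes (4 over the list alone) and of 9 fetal genes (3), and LEFTY2 of 8 pluripotency genes. The other 15 lists had 0 called. TXNIP was the 1 of 12 glucocorticoid-responsive genes called, or 3 over the list alone (adjusted p = 0.146). Leaving out replicate 1 or 3 of 40 h raised the count of 32 to 53 or 51, and summed replicates gave 3.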

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

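All tests of explanations in this part were chosen after the results were seen.

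The 24-h rhythm differed between D15 and D30, by a test of the difference itself, for 16 genes. The 10 with the smallest p were FRZB (6.39), NPY (7.28), DCN (8.92), STMN2 (5.41), CD44 (4.73), RSPO2 (6.59), TMEM17 (2.67), PHF19 (1.65), LUM (4.1) and ISLR (4.31). These values are log2 peak-to-trough sizes of the difference between the fitted curves of D15 and D30. Of 40 random orders of the time points within each day, the real one included, 14 gave as many genes, so chance is not excluded. The highest of the others called 484 genes, which points to a structure of the samples. Without replicate 3 of 20 h at D15 the test called 0 genes by edgeR, where limma called 0 with all libraries, and without replicate 2 of 20 h at D30 it called 10.

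Nearly all tested genes differed between D30 and D15, 6467 against at most 0 in the other 39 of 40 splits within the time points, so a chance split is excluded. GC content of the transcript end as the whole cause is argued against, because 90.8% of the genes were still called after a GC offset per library. Libraries of the days prepared or sequenced apart stay open: the log2 fold changes of 24 ribosomal protein genes had an SD of 1.91, from -3.94 for RPL8 to 2.97 for RPL30, and day and preparation coincide. The biological explanation, differentiation from D15 to D30, was not tested apart from them. For D15 and D30 against D0, 4420 and 6300 genes were called against 0 in any other of the 10 splits, which are too few for a share under 0.05.

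At D15, 1778 genes drifted over the course, and of 100 orders of the time points only the real one gave as many (highest other 292), so chance is excluded. A steady drift stays open: beside a step between 24 h and 28 h the median share of the slope left was 0.28, with quartiles of -0.29 and 1. A response at that time shared by D15 and D30 cells stays open as well, with a median step at D30 of 0.07 (quartiles -0.24 and 0.36) against 0.35 at D15. At D30 the step was called for 0 genes by edgeR, and 728 of 1278 genes (57%) stepped in the direction of their D15 drift. Libraries of the first and last 24 h prepared or sequenced apart could also give such a step, which 35 genes showed at D15, against at most 2 at the other break times there. It stays open because D30 had 44 genes with a step between 36 h and 40 h and 21 between 16 h and 20 h, and because the columns of the D15 parts are not told apart.

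In the 24-h tests at D15 (89 genes) and D30 (73 genes), 14 of 100 orders of the time points gave as many genes at each day, with up to 1156 and 213 in another order, so chance is not excluded for either count and the higher numbers point to a structure of the samples. Varying shares of stromal and neural cells between the cultures could give the D15 calls, since 0 genes were called by edgeR with the fibroblast and neural list means as covariates, and stay open at D30, where 11 were called. Those means follow the hour themselves (42.7% of the variance of the fibroblast mean at D15 and 29.7% at D30 lay in the 24-h terms), so a true rhythm would be lost as well. Depth of the libraries is argued against at D30 (70 genes with the log2 total as covariate) and stays open at D15 (41 genes). A single response after the pulse that does not recur is argued against at D15 for the 19 genes called in the first 24 h alone, whose profiles correlated with those of the last 24 h at a mean of 0.53 (exact permutation p = 0.0111 over 720 orders), and stays open for the other D15 genes (0.36 for the 3 genes called in the last 24 h, p = 0.164, 0 of them among the 89) and at D30 (0.32 over 84 genes, permutation p = 0.0639).

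The drift at D30 called 32 genes, and 9 of 100 orders of the time points gave as many (highest other 140), so chance is not excluded. For lists in the 24-h tests, 2 of 100 orders called as many lists at each day (4 at D15, highest other 4, and 5 at D30, highest other 6).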

How the results depend on the processing

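Steps, fits of 24 h alone, covariates, GC offsets and the omission of a single library were chosen after seeing the data, and the other alternatives were set before. Where a count moved, the cause was not tested, except that fewer genes, time points or libraries enter where some are left out.

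The counts of called genes in the comparisons between days kept within 1.5 times of 4420 and 6300 at 48 h in every alternative run, except that a test against 2-fold called 2143 genes for D15 against D0. For D30 against D15, 6467 genes, no filter on low counts gave 13234, and camera called 1 list with DESeq2's Wald test, 2 with no filter and 7 at 48 h only, against 0. Directions turned with the GC offset for CACNA1H (0.62), ECI1 (0.02) and AFP (-0.01) in D30 against D0, and with the offset and the replicate block for CACNA1H (0.61) and AFP (-0.07). In D30 against D15 they turned for NKX2-5 (1.49), JPH2 (0.35), MYH7 (0.12) and PFKL (0.75), and with the block as well (1.48, 0.35, 0.11 and 0.75). Of values of named genes under the alternatives, 1133 kept their call (or lack of one) and direction and 17 lost the call for D15 against D0. The numbers were 1259 and 26 for D30 against D0 and 1248 and 9 for D30 against D15. The courses lost more: 654 (uncalled core clock genes among them) and 280 in the 24-h test at D15, and 765 and 149 at D30. The difference in rhythm had 269 and 116, the trends 1161 and 146 (D15) and 301 and 66 (D30).

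The 89 genes of the 24-h test at D15 became 163 with DESeq2's likelihood ratio test, 411 with no filter on low counts, 6 with limma, 1 with summed replicates, 39 with no linear trend, 3 at a period of 20 h and 157 at 28 h, and 15 without 4 h and 8 h. Without a replicate number they were 4 to 27, and without a time point 7 to 232: 37 without 8 h, 58 without 12 h, 7 without 20 h, 54 without 24 h, 16 without 28 h, 39 without 32 h, 30 without 36 h, 49 without 40 h and 232 without 44 h. A step between 24 h and 28 h beside the trend left 1, the first 24 h alone 19, the last 24 h alone 3, the omission of replicate 3 of 20 h 16, the fibroblast and neural list means as covariates 0 and the log2 total 41. The 4 lists called there became 2 with DESeq2, 0 with limma, 0 with summed replicates, 2 with no trend, 0 at 20 h, 2 without 4 h and 8 h, 0 beside the step, 1 in the first 24 h, 0 in the last, 1 without replicate 3 of 20 h, 2 without it and with the step in place of the trend, and 0 with the list means as covariates. They were 0 to 1 without a replicate number and 0 to 4 without a time point. The fitted peak moved by more than 6 h for DLK1 without 20 h (peak-to-trough 0.63, with a range of 0.63 to 4.25 over the omissions of a time point). It also did with the list means as covariates for LUM (0.67), TGFBI (0.16), AQP1 (0.23), DLK1 (0.55), SLC9A3R1 (0.42) and CDKN1C (0.69). None of these fits was called (adjusted p from 0.615 to 0.995), so their peak hours carry little meaning.

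The 73 genes at D30 became 187 with no filter, 33 with limma, 4 with summed replicates, 2 at 20 h, 32 without 4 h and 8 h, 110 with the step in place of the trend, 6 in the last 24 h and 11 with the list means as covariates. Without a replicate number they were 5 to 19, and without a time point 11 to 122: 38 without 4 h, 26 without 16 h, 11 without 20 h, 122 without 28 h and 22 without 32 h. The 5 lists became 3 with DESeq2's likelihood ratio test, 2 with limma, 0 with summed replicates, 2 with no trend, 0 at 20 h, 2 without 4 h and 8 h, 1 beside the step, 2 with the step in place of the trend, 2 in the first 24 h, 0 in the last and 2 with the list means as covariates. They were 0 to 2 without a replicate number and 1 to 5 without a time point.

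The 16 genes whose rhythm differed became 9 with DESeq2's likelihood ratio test, 39 with no filter, 0 with limma, 4 with summed replicates, 9 with no trend, 7 at 20 h, 10 without 4 h and 8 h, 6 beside the step, 10 in the first 24 h, 0 in the last and 0 without replicate 3 of 20 h at D15. Without a replicate number they were 0 to 15 and without a time point 0 (20 h) to 23. The fitted peak of the difference moved by more than 6 h without 20 h for FRZB (0.16), DCN (1.25), LUM (1.08) and HAND1 (0.46). None of these 4 was then called (adjusted p from 0.887 to 0.999). Over all omissions of a replicate number, a time point or replicate 3 of 20 h the sizes ran from 0.12 to 8.17, 1.14 to 11.86, 0.88 to 5.57 and 0.35 to 4.36. That peak also moved so in the last 24 h, again without a call, for FRZB (0.55), DCN (1.41) and LUM (1.37).

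The 1778 genes with a trend at D15 became 838 to 1254 without a replicate number, 1455 to 1785 without a time point and 16 with the step beside the trend. LUM turned to a rise without replicate 3 (0.14), without 20 h (0.78) and without replicate 3 of 20 h alone (0.24), with -4.18 without replicate 1. Beside the step the direction turned for CKM (2.61), CYCS (0.61), AURKB (-1.84), COL3A1 (-0.14), CALD1 (-0.34), ENG (-1.0), KRT19 (0.67), KRT7 (1.30), HSPA5 (-0.67) and RPL10A (-0.76). None of these turned slopes was called (adjusted p from 0.0739 for CKM to 0.982 for COL3A1). The 32 genes at D30 became 83 with DESeq2's Wald test, 3 with summed replicates, 8 to 10 without a replicate number, 8 beside the step, and 15 to 158 without a time point: 17 without 4 h, 158 without 40 h, 50 without 44 h and 15 without 48 h. HSPA8 turned to 0.12 beside the step, without a call (adjusted p = 0.952).

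With the replicate number as a block the 24-h tests called 56 genes and 1 list at D15, 72 genes at D30 and 10 for the difference. The trends gave 1717 and 35, D15 against D0 4633, D30 against D0 6401 and D30 against D15 6463, and the block changed no call of a list or named gene in D15 against D0. With the GC offset as well the counts between days were 4429, 5328 and 5953, and the heat shock list was not called in D15 against D0 (adjusted p = 0.051). Whether the numbers pair the libraries is not told by the labels. Deviations of same-numbered libraries correlated at a mean of -0.013 at D15 and 0.014 at D30, against 0.0068 and -0.0071 for other numbers. A library correlated best with its own number in 5 of 36 cases at D15 and 18 of 36 at D30. At 48 h the pairs with D30 lay between -0.016 and 0.0069. Depth limits the courses: genes under about 18.5 CPM may have 0 counts in the shallowest D15 library, and a 2-fold rhythm was recovered for 56.9% of simulated genes at D15.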

Other observations

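The lists of hypoxia and forebrain genes, and all tests of explanations in this part, were chosen after the results were seen.

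Genes of the hypoxia response were among the genes of the 24-h result at D30, and the list was drawn up because some of them were. Of 27 tested genes of a 30-gene list 14 were called, or 20 adjusted over the list alone: ADM, ANKRD37, BNIP3, BNIP3L, DDIT4, EGLN3, HK2, LOX, P4HA1, PFKFB3, PLOD2, SLC2A1, SLC2A3 and VEGFA. They include the angiogenic factor VEGFA, the prolyl hydroxylase EGLN3, which limits the response, and glucose transporters. The mean of the list had a peak-to-trough difference of 0.77 with a peak at 18.4 h, for which no test is given, as its genes were chosen for that pattern. Over the 36 D30 libraries that mean correlated with the mean of the fibroblast list (r = 0.53, against -0.053 at D15), and the fibroblast mean peaked at 19.1 h. With the fibroblast and neural list means as covariates 5 of the 14 were still called, BNIP3, BNIP3L, HK2, PFKFB3 and SLC2A1. At D15, 1 of 22 genes was called, P4HA2. The difference in rhythm was called for 1 of 28, PFKFB3, or 10 adjusted over the list alone.

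Transcripts of forebrain and eye field regulators were found at D30. The CPM that follow were scaled over the libraries of each day apart, and so differ from those of the comparisons between days. PAX6, which specifies eye and forebrain, stood at 245 ± 138 CPM over the 36 D30 libraries against 1.75 ± 2.34 at D15, and FEZF2 at 202 ± 113 against 0.386 ± 1.07. SOX2 stood at 226 ± 129 against 2.81 ± 4.24, and at 597 ± 20.7 in the 3 D0 libraries, while PAX6 was at 0.177 there. RAX, an early eye gene, stood at 21.8 CPM at D30 and 0.412 at D15. All of them were low in the 3 libraries of 40 h at D30: PAX6 at 43.4 ± 11.9, FEZF2 at 36.4 ± 15.7, SOX2 at 40.8 ± 2.15, SFRP2 at 31.2 ± 12.9 against 314 ± 215 over the course, and RAX at 0 counts. In the same libraries the collagen COL3A1 was at 4220 ± 362 CPM against 2720 ± 1060 over the course, and LUM at 1030 ± 116 against 553 ± 337. In the 24-h test 0 of 14 forebrain genes were called by edgeR, with 0 over the list alone and 2 (EMX2 and FABP7) at an unadjusted p under 0.05.

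Between neighbouring time points the largest numbers of genes changed at D30 from 36 h to 40 h (393, 198 higher and 195 lower) and from 40 h to 44 h (80). At D15 they changed from 16 h to 20 h (33) and from 20 h to 24 h (37).

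Profiles of the first and the last 24 h correlated over all tested genes at a mean of 0.074 at D15 (permutation p = 0.0194 over 720 orders) and of 0.089 at D30 (permutation p = 0.00278).

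A hypothesis is that the oxygen response of these cells follows a daily rhythm. It could show at D15 as well, where the mean of the hypoxia list gave a permutation p of 0.881, which leaves the hypothesis open, since culture handling and oxygen supply at D30 were not measured and the fibroblast list moved with the hypoxia list there.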
